A study of Arabidopsis thaliana with 18 samples.

How the data were processed

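Gene expression was measured in petioles of Arabidopsis thaliana accession Col-0 with Affymetrix ATH1 arrays, which carry several short probes per transcript, summarised as 1 value per probe set. The 18 arrays fall into 6 groups of 3. In the density experiment, per the labels' protocols, plants grew alone or in a canopy of 2066 plants per m2, 2 young petioles per plant were taken at an age of 37 d, and petioles of 4 plants made up each biological replicate. In the light experiment, single plants were harvested at an age of 29 d, 24 h after the start of control light, a low red to far-red ratio (low R:FR), low blue light, or low blue light with low R:FR (called combined). All plants had been stratified at 4 °C for 3 d, potted singly after 10 d, and kept until an age of 28 d under 9 h of light at 180 µmol per m2 per s, with 15 h of dark, 20 °C and 70% relative humidity. From each RNA sample 100 ng was labelled with biotin by a 3′ in vitro transcription kit. The protocols do not say whether light replicates came from separate pools of plants, so p-values there measure the spread between these samples, which can be technical.

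The values used were the log2 expression values of 22810 probe sets deposited by the authors, summarised by RMA per the submitters' processing notes. The RMA software, its version and whether other arrays were normalized together are not given in the sources used here. The base of the logarithm was checked on the bacterial control transcripts. Over bioB, the probe sets of bioC, bioD and cre lay higher by 2.51, 4.55 and 6.61, against nominal steps of 1.74, 4.06 and 6.06 in log2 and of 1.2, 2.81 and 4.2 in natural log. Array medians ran from 1.6 to 1.66, single values from 0.44 to 11.4, and 46.8% of probe sets had a mean below 1.5, where differences are compressed. Fold changes of dim genes are therefore understated. No 2 arrays held identical values, and correlations within groups ran from 0.9781 to 0.9939. The number of arrays limits the precision.

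Gene names came from the platform annotation table, with symbols updated through the gene table. Of the 22746 probe sets tested, after 64 control probe sets were set aside, 13513 had 1 gene (13350 genes), 503 had several and were not named, and 8730 were not listed and stay unnamed here. For a gene with several probe sets, that with the highest mean over the 18 arrays was used. Genes without a symbol in these tables are given by their locus.

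limma 3.58.1 in R 4.3.3 was fitted to all 18 arrays with a mean per group and no covariate, followed by eBayes (12 residual and 4.41 prior degrees of freedom). The contrasts were canopy against single plants, each light treatment against control light, combined against each single light treatment, low R:FR against low blue, the interaction of low R:FR and low blue, and the canopy effect minus each light effect. P-values were two-sided and adjusted by Benjamini-Hochberg over the 22746 probe sets within a comparison. A probe set was called at an adjusted p under 0.05. The value after ± is the standard error from limma for a log2 change and the SD over 3 arrays for a level. Canopy and light fold changes, which share no arrays, were compared across probe sets by Pearson and Spearman correlation, and shared calls by Fisher's exact test. Probe sets are not independent replicates, so these describe the profiles. For treatments that share the control arrays, 100 sets of unchanged groups with a common control were simulated. Noise was drawn once independently per probe set and once as deviations of whole arrays among the 18, which keep the correlation between genes. The control was simulated as well, so it varied like the groups in general and not like control light in particular.

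Gene lists were fixed before the data were examined: 30 lists, of which the annotation named 47 of 355 genes. Only 8 lists had 3 or more named members and were tested. A further 14 lists had 1 or 2 named members and 8 had none, and 1 member was left out because symbol and locus disagreed. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Another 30 lists were drawn from the symbols of the annotation table after it was opened and before any group difference was computed. The rule for named genes was fixed before the data were examined. It took, in each of canopy, low R:FR, low blue and combined against their controls, the 8 highest and 8 lowest changes among called probe sets of 1 gene whose 3 arrays in one group all lay above the 3 of the other, a separation that chance gives 10% of the time. In each of the next 4 comparisons it took 4 highest and 4 lowest, for the interaction without the separation. It also took up to 4 called members of each list described, or the member with the largest change where none was called, and members called in 1 light treatment and tested for a difference from another. In every comparison it further took PIL1, HFR1, ATHB2, IAA19, IAA29, YUC8, YUC9, XTH15, XTH17, TT4, PIF4, PIF5 and HY5, of which IAA29 had a named probe set here.

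The fit was tested on simulated data for canopy against single plants over 22746 probe sets. Noise was drawn independently per probe set, and the changed probe sets were drawn from those with a mean above the median. It recovered 11 of 67 probe sets changed by 0.5 on the log2 scale (16.4%), 56 of 67 changed by 1 (83.6%) and 65 of 66 changed by 2 (98.5%), with 9 false among 141 calls. In a simulation over 13350 genes, 1 list of 10 genes shifted by 0.5 was called and 0 of the others among the 30 lists were. These lists were random and their genes uncorrelated by construction, so this says nothing about false calls of lists of correlated genes. Replicate numbers come from the labels, and whether they pair arrays was read from the deviations of arrays from their group means. In the density experiment the 3 pairs of the same number correlated at 0.21, 0.426 and 0.101, but single replicate 1 and canopy replicate 3 also at 0.214. Pairing is therefore possible there but not shown. The main fit leaves it out, and a block by replicate number was fitted as an alternative. The light arrays were not read as paired. Alternatives were quantile normalization, median centring, leaving out the dimmest 30% of probe sets, leaving out probe sets that can share transcripts, an intensity trend with robust moderation, array weights, fits within each experiment, the replicate number as a block, a log2 change of at least 1, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.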

Results

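Transcript levels were measured in petioles, the leaf stalks that elongate in crowded rosettes, on 18 arrays in 6 groups of 3. A density experiment set plants in a canopy of 2066 plants per m2 against single plants, both 37 d old. A light experiment exposed single plants of 29 d for 24 h to control light, low R:FR, low blue light or both together. By its title, the series asks how far these light signals enter the response to competition at high density. Low R:FR is sensed by phytochromes and blue light by cryptochromes and phototropins. Array medians lay between 1.6 and 1.66 on the log2 scale.

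**Figure D1:**
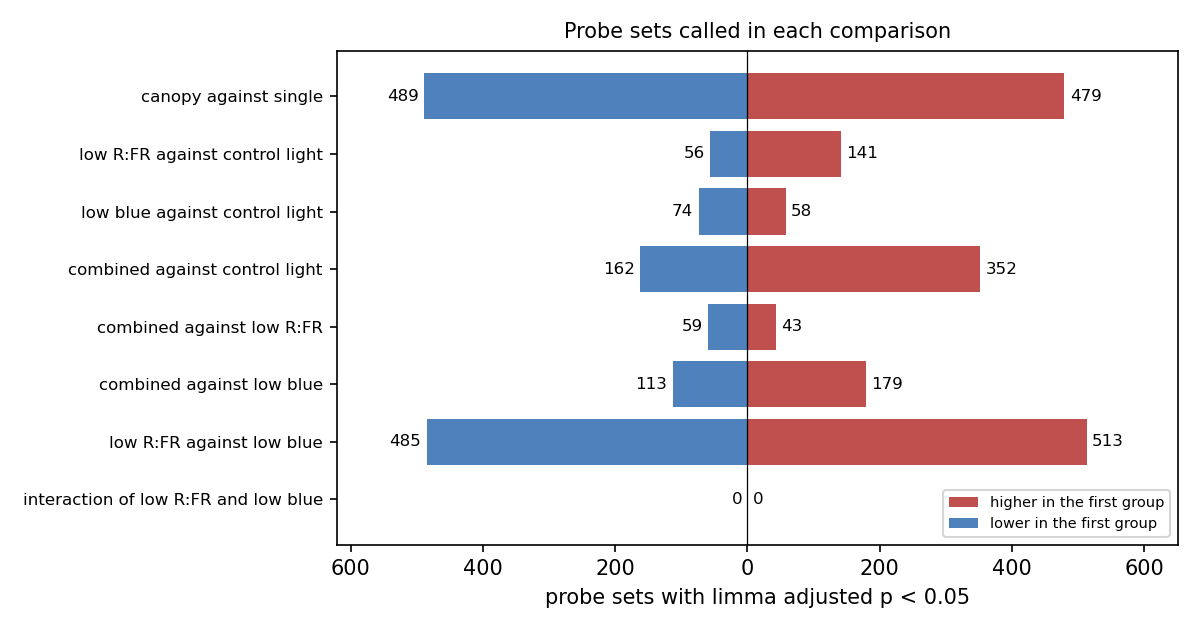
Number of probe sets with a limma adjusted p under 0.05 in each comparison (horizontal axis), split into those higher and those lower in the first group (n = 3 arrays per group). The canopy changed 968 probe sets, low R:FR 197, low blue 132 and the combined treatment 514.

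In petioles from the canopy, the expansin EXPA8, which loosens cell walls, rose 5.05-fold, from 3.78 ± 0.27 to 6.11 ± 0.21 on the log2 scale (SD, n = 3; limma adjusted p = 3.9e-05). AT3G15450 rose 13.4-fold (log2 change 3.75 ± 0.46, adjusted p = 0.00012), and AT2G20670, AT2G41250, AT1G49500, AT5G11070 and AT3G06070 rose by 2.17 to 2.82. The bZIP transcription factor gene BZIP61 rose by 2.13 ± 0.28. Of the named genes AT5G20790 fell most, from 7.08 ± 0.68 to 1.53 ± 0.35 (log2 change -5.55 ± 0.78, adjusted p = 0.00041), a level near the floor of the arrays. CHX20, a cation/proton exchanger gene, and the β-glucosidase gene BGLU47 both had a log2 change of -2.1, AT1G06000 of -2.06 ± 0.18 and AT5G53420 of -2.22 ± 0.2. AT4G34950, AT2G16660 and AT1G23140 fell as well, with log2 changes of -2.07, -2.6 and -1.99.

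Counts for the fixed gene lists cover only members with a named probe set, such as 4 of 16 auxin response genes. Of these 4, 2 rose in the canopy. The auxin-inducible repressor gene IAA29 rose by 1.14 ± 0.21 (adjusted p = 0.0038). It lay at 0.79 to 1.15 on single plant arrays and at 1.11 to 1.39 in control light, near the floor. The sizes of its changes against these groups are therefore uncertain. The auxin-conjugating GH3 gene WES1 rose by 0.93 ± 0.15 (0.0014). Both were also higher when adjusted over the list alone, and the list shifted up (camera adjusted p = 0.0083; adjusted p = 0.07 with an estimated correlation). Of the 4 xyloglucan endotransglucosylase/hydrolase (XTH) genes of the fixed list, whose products remodel wall xyloglucan, XTH33 rose by 0.72 ± 0.17, and 3 were higher adjusted over the list alone. That list shifted up at an adjusted p of 0.0029 (adjusted p = 0.081 with an estimated correlation). The expansins moved apart, with EXPA8 higher and EXPA4 lower (-1.56 ± 0.27, adjusted p = 0.002), the same 1 and 1 adjusted over the list alone, a median of -0.15 and a camera direction that was up (adjusted p = 0.9). The dehydrin genes COR47 and LTI30, of the abscisic acid and water deficit list, rose by 1.09 ± 0.14 and 1.54 ± 0.18. Of the 4 members of this list, 2 were higher and 1 lower adjusted over the list alone, and it shifted up (adjusted p = 0.024; adjusted p = 0.11 with an estimated correlation). In the list of light-harvesting antenna genes, LHCB4.3 had a log2 change of -1.42 ± 0.16 (adjusted p = 6.7e-05), the 1 of 3 lower adjusted over the list alone, and the list shifted down (adjusted p = 0.018; adjusted p = 0.1 with an estimated correlation). The clock gene GI had a log2 change of -0.95 ± 0.14 (adjusted p = 0.00083).

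Gibberellin genes (3 with a named probe set, list adjusted p = 0.37), senescence genes (0.078) and epidermal markers (0.41) did not shift as lists in the canopy. No member was called in them, and adjusted over the list alone 1 senescence gene was lower, with SAG29 at -0.37 ± 0.1 (adjusted p = 0.055 over all probe sets), GID1A at -0.2 ± 0.15 for gibberellin and the guard cell gene FMA at -0.24 ± 0.14. The root marker PYK10 was higher in the canopy, by 1.69 ± 0.45 (adjusted p = 0.041), at a mean over all arrays of 1.76. RCA, a marker of the leaf blade mesophyll, changed by -0.19 ± 0.09 (adjusted p = 0.35), and the phloem gene SWEET11 by -0.02 ± 0.11 (0.97).

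In all, limma called 968 of 22746 probe sets, 479 higher and 489 lower, 346 by at least 1 on the log2 scale, and 414 of them carried 1 named gene. The count was 554 without single replicate 3 and 571 without canopy replicate 2. Leaving out 1 array ended the call of AT2G16660 (highest adjusted p = 0.058, without canopy replicate 2), of AT1G23140 (0.063) and XTH33 (0.11) without single replicate 3, and of PYK10 (0.19) without single replicate 1. Over the 6 leave-outs PYK10 lost its call in 5, XTH33 in 3, and AT2G16660 and AT1G23140 in 2 each. In a fit of the density arrays alone the calls of AT2G16660 (0.052) and PYK10 (0.093) ended, that of PYK10 also with an intensity trend (0.1), and the shift of the water deficit list ended without single replicate 1 (0.075).

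**Figure D2:**
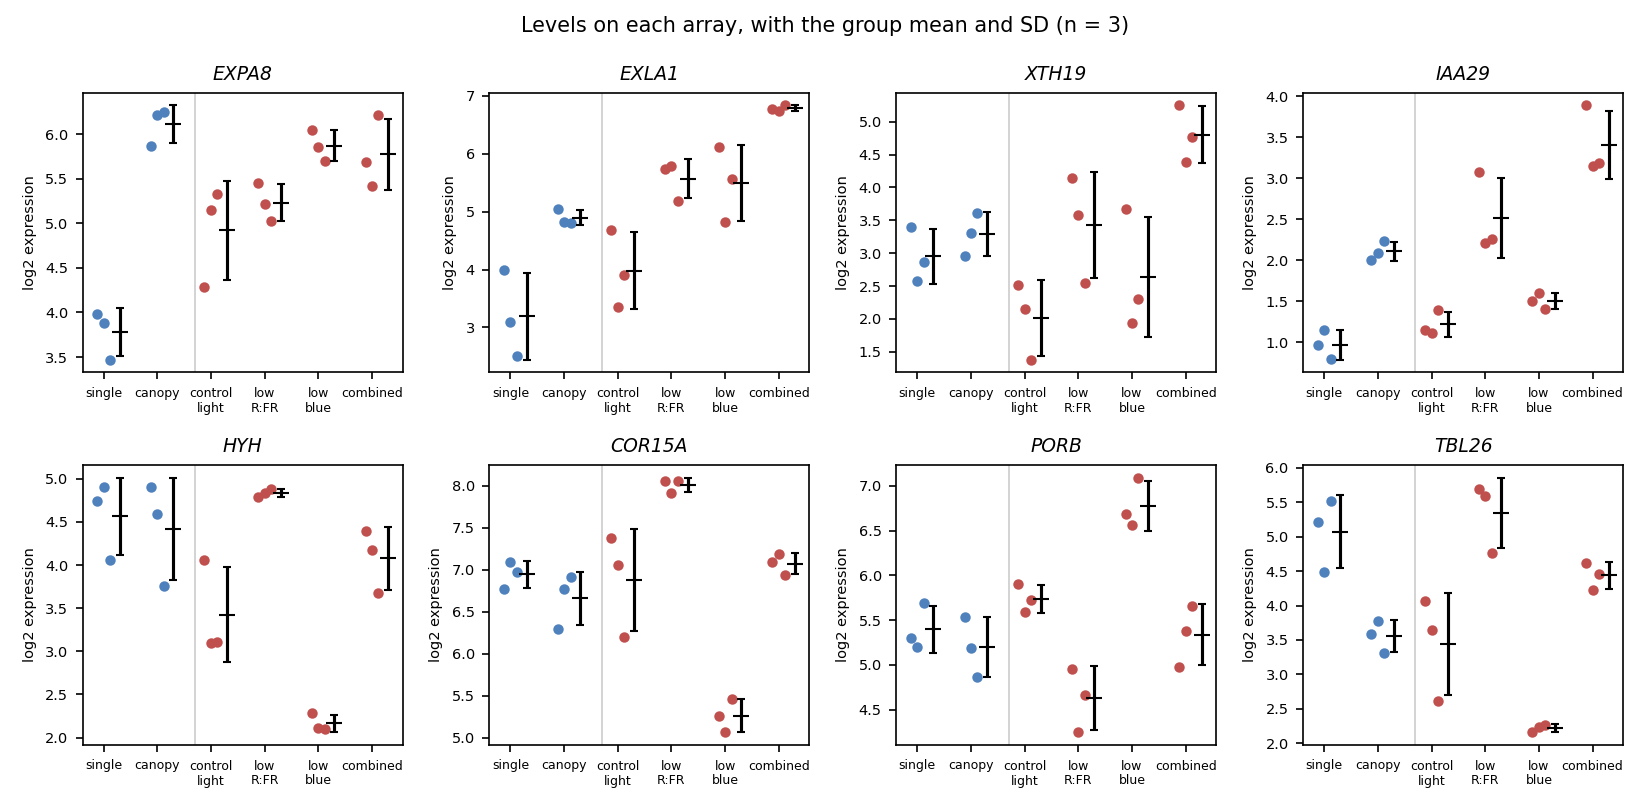
Levels of 8 named genes (vertical axis, log2 expression) on each array (points, blue for the density and red for the light experiment), with the group mean and SD (bars, n = 3). XTH19 and IAA29 were highest in the combined treatment, and COR15A and PORB moved in opposite directions in low R:FR and low blue.

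After 24 h of low R:FR, TBL26, a gene of the trichome birefringence-like family of wall polysaccharide acetylation, rose 3.75-fold (log2 change 1.91 ± 0.32, adjusted p = 0.0062). AT4G25260 rose by 1.72 ± 0.15 (adjusted p = 2.6e-05), MGL, which encodes methionine gamma-lyase, by 1.41 ± 0.15 (0.00014), and AT3G56290 by 1.82 ± 0.24 (0.00092). HYH, a bZIP factor that acts with HY5 in light signalling, rose by 1.41 ± 0.29 (0.028), and AT5G66590, AT1G70985 and AT3G28220 by 1.58 to 1.8. PORB, which encodes a protochlorophyllide oxidoreductase of chlorophyll synthesis, had a log2 change of -1.11 ± 0.22 (adjusted p = 0.018). AT3G23080, AT1G74940, AT4G00780, AT5G55530, AT1G56220, AT3G22970 and AT1G67750 were lower as well, from -1.76 ± 0.32 for the first to -1.08 ± 0.23 for the last.

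IAA29 rose by 1.3 ± 0.21 in low R:FR (adjusted p = 0.0052), the 1 of 4 auxin response genes called, also adjusted over the list alone, and the list shifted up (adjusted p = 0.0031; adjusted p = 0.038 with an estimated correlation). None of the 4 XTH genes of the fixed list was called over all probe sets, but 3 were higher adjusted over the list alone and the list shifted up (adjusted p = 0.00032; adjusted p = 0.038 with an estimated correlation), with XTH19 at 1.41 ± 0.44 and XTH16 at 1.24 ± 0.33. In a wider list of 10 XTH genes, added after the annotation was opened, 0 were called and the shift had an adjusted p of 0.038 (adjusted p = 0.18 with an estimated correlation). COR15A, which encodes a cold-regulated chloroplast protein, rose by 1.13 ± 0.22 (adjusted p = 0.02), the 1 of 4 water deficit genes called, also adjusted over the list alone, and that list shifted up (adjusted p = 0.0028; adjusted p = 0.041 with an estimated correlation). The expansin, gibberellin, antenna, senescence and epidermis lists did not shift (adjusted p from 0.13 to 1), and adjusted over the list alone 1 gibberellin and 1 antenna gene were lower. Their members with the largest changes were EXPA15 at 0.42 ± 0.25, GID1A at -0.45 ± 0.15, LHCB4.2 at -0.31 ± 0.1, WRKY53 at -0.35 ± 0.33 and FMA at -0.26 ± 0.14.

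Low R:FR changed 197 probe sets, 141 higher and 56 lower, 97 of them by at least 1 on the log2 scale, and 457 were called with array weights. Control light replicates 1 and 3 correlated least of all pairs within a group (0.9781), and without both, an alternative chosen after the data were seen, 37 were called. The count moved with every array left out, to 472, 119 and 84 without control light replicates 1, 2 and 3 and to 119, 80 and 109 without low R:FR replicates 1, 2 and 3. With 1 array left out the highest adjusted p was above the threshold for AT3G28220 (0.25), HYH (0.16), AT3G23080 (0.075), AT4G00780 (0.055), AT5G55530 (0.063) and AT1G67750 (0.21) without control light replicate 3, for PORB (0.13), AT1G56220 (0.093), AT1G74940 (0.053) and AT3G22970 (0.055) without low R:FR replicate 2, for COR15A (0.08) without low R:FR replicate 3 and for AT1G70985 (0.071) without low R:FR replicate 1. AT3G28220, HYH and AT1G67750 lost the call in 5 of 6 leave-outs, AT1G56220 and COR15A in 4, and PORB, AT3G23080 and AT1G70985 in 3. AT4G00780 and AT5G55530 lost it in 2, and AT1G74940 and AT3G22970 in 1. The call of AT3G28220 ended with an intensity trend (0.075) and that of AT1G67750 in a fit of the light arrays alone (0.055).

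In low blue light, BZIP61 rose 2.8-fold (log2 change 1.49 ± 0.28, adjusted p = 0.026) and AKINBETA1, a regulatory subunit gene of the energy-sensing kinase SnRK1, rose by 1.34 ± 0.22 (0.012). AT1G35612 (1.57 ± 0.21), AT4G27450 (1.5 ± 0.16), AT1G25230 (1.48 ± 0.16), AT2G30930, AT5G11070 and AT4G37240 rose too. COR15A had a log2 change of -1.62 ± 0.22 (adjusted p = 0.0038), LHCB4.3 of -1.07 ± 0.16 (0.0045), and THIC, of thiamine synthesis, of -0.95 ± 0.15 (0.0068). UGT78D1, a flavonol rhamnosyltransferase gene, was also lower at -0.95 ± 0.2 (0.044), as were AT3G56290 (-1.54 ± 0.24), AT1G06000 (-1.29 ± 0.18), AT3G44450 (-0.97 ± 0.19) and AT3G57020 (-0.96 ± 0.2).

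None of the 4 XTH genes of the fixed list was called in low blue, 2 were higher adjusted over the list alone, and the list shifted up (adjusted p = 0.0012; adjusted p = 0.096 with an estimated correlation), with XTH16 at 1.1 ± 0.33. The wider list of 10 XTH genes had 1 called and did not shift (adjusted p = 0.072; adjusted p = 0.27 with an estimated correlation). The water deficit list shifted down (adjusted p = 0.0077; adjusted p = 0.096 with an estimated correlation), with COR15A called and 2 lower and 1 higher adjusted over the list alone. The auxin response list did not shift (adjusted p = 0.15), with IAA29 at 0.28 ± 0.21, and neither did the antenna list (0.15), in which LHCB4.3 was called and 1 was higher and 1 lower adjusted over the list alone. Expansins, gibberellin, senescence and epidermis genes had no called member and list adjusted p-values from 0.58 to 0.78. Their largest changes were EXPA8 at 0.95 ± 0.24, the 1 expansin higher adjusted over the list alone, GID1A at -0.45 ± 0.15, the 1 gibberellin gene lower in the same sense, WRKY53 at 0.06 ± 0.33 and SPCH at -0.17 ± 0.1.

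Low blue changed 132 probe sets, 58 higher and 74 lower, 45 of them by at least 1, and 18 were called without control light replicates 1 and 3. The count was 85 and 30 without control light replicates 1 and 2, and 85 and 51 without low blue replicates 1 and 3. With 1 array left out the highest adjusted p passed the threshold for AT5G11070 (0.17), AT2G30930, AT4G37240 and AT3G44450 (0.13 each), AKINBETA1 (0.07), THIC (0.055) and AT3G56290 (0.052) without control light replicate 2, for UGT78D1 (0.13) without control light replicate 1, for BZIP61 (0.11) without low blue replicate 3 and for AT3G57020 (0.14) without low blue replicate 1. AT5G11070 lost the call in 6 of 6 leave-outs, UGT78D1 and AT3G57020 in 5, and BZIP61, AT2G30930, AT4G37240 and AT3G44450 in 4. AKINBETA1, THIC and AT3G56290 lost it in 1. In a fit of the light arrays alone the calls of AT3G57020 (0.061) and UGT78D1 (0.084) ended. The XTH and water deficit shifts ended without low blue replicate 1 (0.069 each), the latter also without control light replicate 1 (0.072), while the antenna list passed after quantile normalization (0.036).

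With low blue and low R:FR combined, EXLA1, an expansin-like gene, rose 6.98-fold from 3.98 ± 0.67 to 6.79 ± 0.05 (SD, n = 3; limma adjusted p = 0.00037), XTH19 by 2.79 ± 0.44 and XTH16 by 2.59 ± 0.33. EXO, a gene of brassinosteroid-promoted growth, rose by 2.13 ± 0.46, AT1G69570 by 2.44 ± 0.16 and AT4G25260 by 2.17 ± 0.15. BZIP61 rose by 2.39 ± 0.28 and IAA29 by 2.19 ± 0.21 (adjusted p = 2e-05). UGT74B1, a glucosyltransferase gene of glucosinolate synthesis, had a log2 change of -1.31 ± 0.17 (0.0004), AT4G24780 of -1.36 ± 0.14 and AT1G67860 of -2.18 ± 0.49. AT1G74940, AT4G34950, AT3G22970, AT1G14890 and HL fell too, with log2 changes of -1.8, -1.57, -1.54, -1.52 and -1.37.

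All 4 XTH genes of the fixed list rose in the combined treatment, also adjusted over the list alone, with XTH33 at 1.22 ± 0.17 and XTH18 at 1.13 ± 0.12, and the list shifted up (adjusted p = 4.5e-14; adjusted p = 0.00062 with an estimated correlation). IAA29 and WES1 (0.84 ± 0.15) rose among 4 auxin response genes, the same 2 adjusted over the list alone, and that list shifted up (adjusted p = 2.4e-06; adjusted p = 0.0011 with an estimated correlation). HAT2, a homeodomain gene of the low R:FR response list, rose by 1.26 ± 0.12 (adjusted p = 2.4e-05). The antenna list shifted down (adjusted p = 0.0087; adjusted p = 0.073 with an estimated correlation) with no member called and 2 of 3 lower adjusted over the list alone, LHCB4.3 among the 3 at -0.61 ± 0.16. GID1A, a gibberellin receptor gene, had a log2 change of -0.66 ± 0.15 (adjusted p = 0.027), the 1 of 3 also lower adjusted over the list alone, while its list (adjusted p = 0.58) and those of the 4 expansins (0.93), water deficit (0.9), senescence (0.58) and epidermis (0.93) did not shift. A wider list of 18 expansin and expansin-like genes, added after the annotation was opened, shifted up with the expansin-like EXLA1, EXLA2 and EXLA3 called (adjusted p = 0.0011; adjusted p = 0.038 with an estimated correlation). Adjusted over the list alone, 1 expansin was higher and 1 lower and 1 water deficit gene was higher. EXPA4 stood at -0.86 ± 0.27, COR47 at 0.42 ± 0.14, SAG29 at -0.16 ± 0.1 and FMA at -0.21 ± 0.14.

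The combined treatment changed 514 probe sets, 352 higher and 162 lower, 197 of them by at least 1, and 112 were called without control light replicates 1 and 3. The count was 310 and 341 without control light replicates 2 and 3, and 276 without combined replicate 2. With 1 array left out the highest adjusted p passed the threshold for EXO (0.097) and AT1G14890 (0.2) without combined replicate 2, AT4G34950 (0.086) without combined replicate 1, AT1G67860 (0.1) without control light replicate 3 and GID1A (0.14) without control light replicate 2. AT1G67860 lost the call in 5 of 6 leave-outs, and EXO, AT1G14890, AT4G34950 and GID1A in 4. With an intensity trend the calls of EXO (0.058), AT1G67860 (0.07) and AT1G14890 (0.078) ended and LHCB4.3 passed (0.038), and the antenna shift ended without control light replicate 1 or combined replicate 1 (0.052 each).

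Added to low R:FR, low blue raised XTH18 by 0.82 ± 0.12 (adjusted p = 0.0037), XTH33 by 0.96 ± 0.17 (0.012) and HAT2 by 0.91 ± 0.12 (0.0027). All 4 XTH genes of the fixed list were higher adjusted over the list alone, and the list shifted up (adjusted p = 3.5e-10; adjusted p = 0.0027 with an estimated correlation). AT2G30930, AT4G27280, AT2G30600 and AT1G22330 were higher by 1.26 to 1.53. The other probe sets of AT2G30600 and AT1G22330 gave 0.26 (adjusted p = 0.77) and 0.91 (0.1). AT2G27420 had a log2 change of -2.21 ± 0.34, AT5G05250 of -1.87 ± 0.29, AT1G06000 of -1.55 ± 0.18, and CHIL, a chalcone isomerase-like gene of flavonoid synthesis, of -1.58 ± 0.31 (adjusted p = 0.028). LHCB4.3 was lower too, at -0.88 ± 0.16 (0.015). The auxin response list shifted up with no member called and 2 higher adjusted over the list alone (adjusted p = 0.0027; adjusted p = 0.019 with an estimated correlation). The water deficit list shifted down with 2 lower adjusted over the list alone (adjusted p = 0.0036; adjusted p = 0.054 with an estimated correlation). The other 5 lists had adjusted p-values from 0.12 to 0.74.

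This comparison called 102 probe sets, 43 higher and 59 lower, with 48 changed by at least 1 and 200 called with array weights, and 60, 52 and 53 without low R:FR replicates 1, 2 and 3, and 63 and 64 without combined replicates 1 and 3. With 1 array left out the highest adjusted p was 0.12 for AT2G30930 and 0.16 for AT2G30600 without low R:FR replicate 1, 0.067 for AT4G27280 and 0.063 for AT1G22330 without low R:FR replicate 2, 0.17 for CHIL and 0.087 for LHCB4.3 without low R:FR replicate 3, and 0.073 for XTH33 without combined replicate 3. CHIL lost the call in 6 of 6 leave-outs, AT2G30930, AT2G30600 and LHCB4.3 in 5, XTH33 in 4, AT1G22330 in 3 and AT4G27280 in 2. The call of LHCB4.3 ended in a fit of the light arrays alone (0.063), and IAA29 (0.89 ± 0.21, adjusted p = 0.087) passed with an intensity trend (0.03).

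Added to low blue, low R:FR raised AT3G56290 by 2.37 ± 0.24 (adjusted p = 7.9e-05), TBL26 by 2.21 ± 0.32 (0.0013), XTH19 by 2.17 ± 0.44 (0.019) and HYH by 1.92 ± 0.29 (0.0023). IAA29 was higher by 1.9 ± 0.21 (0.00014) and COR15A by 1.81 ± 0.22 (0.00029). AT3G15630 had a log2 change of -2.53 ± 0.51, AT3G10020 of -2.43 ± 0.36, AT1G14890 of -1.96 ± 0.37 and AT1G74940 of -1.56 ± 0.26. All 4 XTH genes of the fixed list rose, also adjusted over the list alone, and the list shifted up (adjusted p = 7.4e-10; adjusted p = 0.0031 with an estimated correlation). The auxin response list, with 2 higher adjusted over the list alone, and the water deficit list, with 1, shifted up (adjusted p = 0.00012 and 0.0026; adjusted p = 0.0046 and adjusted p = 0.047 with an estimated correlation). The other 5 lists had adjusted p-values from 0.46 to 0.55.

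This comparison called 292 probe sets, 179 higher and 113 lower, with 126 changed by at least 1, and 135 without low blue replicate 2, 177 without combined replicate 1 and 124 without combined replicate 2. The highest adjusted p was 0.11 for XTH19, 0.18 for XTH16 and 0.084 for AT3G15630 without low blue replicate 2, and 0.071 for AT1G14890 without combined replicate 2. XTH19, XTH16 and AT3G15630 lost the call in 4 of 6 leave-outs and AT1G14890 in 2. In a fit of the light arrays alone the calls of XTH19 (0.055), XTH16 (0.059), XTH33 (0.11) and AT3G15630 (0.062) ended, those of XTH19 (0.052) and AT3G15630 (0.056) also with an intensity trend.

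Low R:FR and low blue, set directly against each other, differed at more probe sets than either did from control light. AT3G56290 was 10.3-fold higher in low R:FR (log2 change 3.37 ± 0.24, adjusted p = 4.5e-07), TBL26 8.71-fold, AT5G57785 7.9-fold and COR15A 6.73-fold (2.75 ± 0.22, 2.1e-06). HYH was higher by 2.67 ± 0.29, LHCB4.3 by 1.34 ± 0.16, IAA29 by 1.01 ± 0.21 and GI by 0.8 ± 0.14. LHCB4.2, of the same antenna list as LHCB4.3, was called lower in low R:FR, at -0.63 to -0.44 over the leave-outs. AT3G15630 was 10.2-fold lower in low R:FR, AT3G15450 9.01-fold, AT3G10020 7.46-fold and AT3G23080 5.25-fold. PORB, lower in low R:FR and higher in low blue (1.04 ± 0.22, adjusted p = 0.042) against control light, differed by -2.15 ± 0.22 (1.7e-05). COR15A and AT3G56290 were called against control light in both treatments too, higher in low R:FR and lower in low blue. The water deficit list was higher in low R:FR, with 3 of 4 higher adjusted over the list alone (adjusted p = 0.00011; adjusted p = 0.028 with an estimated correlation), and the other 7 lists had adjusted p-values of 0.43 or 0.83.

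The direct comparison called 998 probe sets, 513 higher and 485 lower in low R:FR, with 303 changed by at least 1, and 569 and 649 without low R:FR replicates 2 and 3. Of the 998, 231 were called against control light in either treatment. Without control light replicate 2 the call of PORB in low blue ended (adjusted p = 0.17; 0.051 in a fit of the light arrays alone), as did that of AT3G56290 (0.052). In low R:FR the calls of PORB and COR15A ended without low R:FR replicate 2 (0.13) and 3 (0.08), and that of HYH without control light replicate 3 (0.16). PORB lost its low blue call in 5 of 6 leave-outs, and HYH, COR15A and PORB lost their low R:FR calls in 5, 4 and 3.

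Calls against control light shared direction in 77 higher and 26 lower probe sets between low R:FR and combined, where independent lists would share 2.2 and 0.4, and none was opposite. Between low blue and combined 25 higher and 18 lower were shared (0.9 and 0.5 for independent lists) and 0 opposite. Between low R:FR and low blue 7 were shared and 17 opposite, COR15A, PORB and AT3G56290 among the 17. Across probe sets the fold changes correlated at r = 0.714 (covariance 0.0525), 0.539 (0.0337) and 0.178 (0.0101) in these pairs. Simulated unchanged groups with a common simulated control gave a mean covariance of 0.0156, from -0.0061 to 0.053, with whole-array noise. With independent noise it was 0.0127, from 0.0119 to 0.014. Each observed covariance lay within the range with whole-array noise, so an excess over shared controls was not shown. The numbers for independent lists do not allow for shared controls either. With 3 control arrays the controls could not be split with 2 arrays on each side. All or part of the sharing between treatments can therefore come from the shared controls. Of the 514 combined calls, 103 were also called in low R:FR, 43 in low blue, 7 in both and 375 in neither.

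The interaction asks whether the combined change departs from the sum of the single changes on the log2 scale. AT4G27450, named here after its values were seen, departed by -1.48 ± 0.22, with the smallest adjusted p of any probe set (0.096). It rose in low blue to a level of 2.87 ± 0.25, while control light (1.38), low R:FR (1.43) and combined (1.44) lay below 1.5, near the floor of the arrays, so the size of the departure is uncertain. AT5G05250, chosen likewise, departed by -2.05 ± 0.41 (adjusted p = 0.98). XTH18 departed by 0.57 ± 0.17 and was the 1 XTH gene of the fixed list higher adjusted over the list alone, HAT2 by 0.7 ± 0.18, XTH19 by 0.75 ± 0.62 and IAA29 by 0.61 ± 0.3, each of these 4 with an adjusted p of 1 over all probe sets. For IAA29 the size is uncertain too, as it lay at 1.11 to 1.39 in control light and 1.41 to 1.6 in low blue, near the floor. The XTH list was higher in the combined treatment than the sum (adjusted p = 0.0075; adjusted p = 0.15 with an estimated correlation), and the other 7 lists had adjusted p-values from 0.084 to 0.96. limma called 0 probe sets, with 811 at an unadjusted p under 0.05, 437 higher and 374 lower, where 1137 are expected by chance. An intensity trend with robust moderation called AT4G27450 (adjusted p = 0.0098), and a fit of the light arrays alone called AT5G05250 (0.0094). The shift of the XTH list ended without control light replicate 1 (0.13), low R:FR replicate 3 (0.062) or low blue replicate 2 (0.13).

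**Figure D3:**
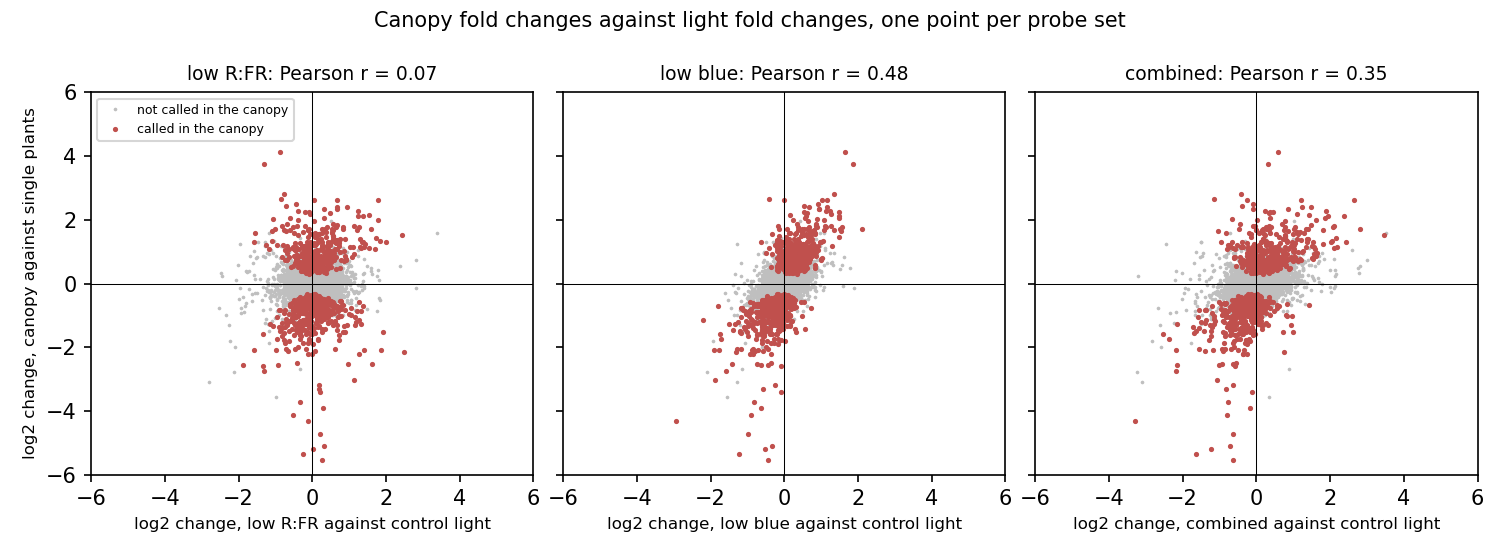
Log2 change of each probe set in the canopy (vertical axis) against its log2 change in low R:FR, low blue or the combined treatment (horizontal axis), with probe sets called in the canopy in red. The correlation was 0.071 with low R:FR, 0.476 with low blue and 0.353 with the combined treatment.

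Canopy changes were set beside those of each light signal. BZIP61 and AT5G11070 rose in the canopy and in low blue, BZIP61 also in low R:FR (1.38 ± 0.28, adjusted p = 0.027), and LHCB4.3, UGT78D1 (-1.01 ± 0.2 in the canopy) and AT1G06000 fell in both. TBL26 fell in the canopy (-1.52 ± 0.32, adjusted p = 0.0094) and rose in low R:FR, a difference of -3.43 ± 0.45 (0.00064). IAA29 rose in the canopy, in low R:FR and in the combined treatment. The canopy effect on LTI30 lay above those of low R:FR (1.35 ± 0.25, adjusted p = 0.0086), low blue (1.87 ± 0.25, 0.0064) and combined (1.69 ± 0.25, 0.0062). The differences from low blue and combined exceed its canopy rise, so its estimates there were not higher than in control light. EXPA8 rose more in the canopy than in low R:FR (2.02 ± 0.34, 0.0043), while its differences from low blue (1.39 ± 0.34, 0.15) and combined (1.48 ± 0.34, 0.054) did not pass. The canopy effect lay below the combined effect for HAT2 (-0.81 ± 0.18, 0.04) and XTH18 (-0.82 ± 0.17, 0.034). HAT2 stood at 0.45 ± 0.12 in the canopy (adjusted p = 0.051; adjusted p = 0.04 with the replicate number as a block and 0.047 after quantile normalization). The canopy call of TBL26 ended without single replicate 3 (adjusted p = 0.064). The low blue calls of BZIP61, AT5G11070 and UGT78D1 ended in 4, 6 and 5 of 6 leave-outs. Their highest adjusted p came without low blue replicate 3 (0.11) and control light replicates 2 (0.17) and 1 (0.13). The low R:FR call of BZIP61 ended without control light replicate 3 (0.16) and without low R:FR replicates 1 (0.1), 2 (0.1) and 3 (0.075).

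Of the 968 canopy calls, 87.4% had the same sign in low blue, 77.9% in combined and 56.2% in low R:FR. Calls shared in direction numbered 74 with low blue (31 higher, 43 lower, 1 opposite; Fisher's exact p = 6.3e-37 and 1.1e-52), 166 with combined (107, 59, 6 opposite; exact p = 8.8e-95 and 1.5e-56) and 39 with low R:FR (32, 7, 29 opposite; exact p = 4.8e-24 and 0.00019). Independent lists would share 2.8, 10.9 and 4.2 in the same direction. The exact tests take each direction alone and do not weigh the opposite calls. With 29 opposite, the tests for low R:FR therefore do not show agreement in direction. Of the low R:FR calls 53.3% had the same sign in the canopy, against 91.7% of low blue and 82.7% of combined calls. Over all 22746 probe sets the canopy changes correlated with low blue at r = 0.476 (rho = 0.292, jackknife SE 0.086 over 12 arrays), with combined at 0.353 (0.191, 0.1) and with low R:FR at 0.071 (0.03, 0.143). The shared count with low R:FR was 65, 25 and 21 without control light replicates 1, 2 and 3 and 23 and 25 without low R:FR replicates 2 and 3; that with low blue was 44 without single replicate 3, 39 without canopy replicate 2, 21 without control light replicate 2 and 48 and 29 without low blue replicates 1 and 3; that with combined was 110 without single replicate 3 and 106 without canopy replicate 2 or control light replicate 2.

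The canopy effect differed from the low R:FR effect at 473 probe sets (221 higher, 252 lower), from the combined effect at 182 (84, 98) and from the low blue effect at 26 (16, 10), or 40 with the replicate number as a block. AT3G15450 (5.05 ± 0.64, adjusted p = 0.00055), AT1G35612 (2.33 ± 0.29, 0.00042) and AKINBETA1 (2.45 ± 0.32, 0.00059) changed more towards higher levels in the canopy than in low R:FR, and AT1G06000 (-2.68 ± 0.26, 5.8e-05) and MGL (-1.49 ± 0.21, 0.0013) more towards lower levels. Age and duration differed between the experiments and cannot be told apart from these differences. The count against low blue was 77 without single replicate 2, 13 without single replicate 3, 14 without canopy replicate 2 and 17 without low blue replicate 2; that against combined was 94 and 100 without single replicates 1 and 3, 88 and 77 without canopy replicates 2 and 3, 83 and 114 without control light replicates 2 and 3, and 73 without combined replicate 2.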

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

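Tests chosen only after the result was seen were those of the shared control arrays, of the replicate number in each experiment, of other splits for the interaction and of splits that part pairs. No result met the fixed criteria for a closer look. Single outlying values were not tested in groups of 3 arrays.

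Canopy fold changes correlated more with low blue than with low R:FR fold changes. With the shared axis of variation removed, over 9795 probe sets, the difference in r was 0.541, from 0.467 to 0.578 over the leave-outs. This argues against that axis as the whole cause. With the axis kept, over all 22746 probe sets, r was 0.476 with low blue and 0.071 with low R:FR. The difference between these was never below 0.309 over the leave-outs, the value without single replicate 2, so no single array decides it. Low blue calls shared the canopy direction more often than low R:FR calls by 38.4 percentage points (31.6 to 42.9), against a weaker measured low R:FR response as the cause. The canopy and low R:FR effects of LHCB4.3 differed by -1.69 ± 0.22 (limma adjusted p = 0.00067), while its combined change of -0.61 was not called. That it follows low blue rather than low R:FR in a canopy is a hypothesis. The tests above span many probe sets and do not test this gene. Plant age and duration of exposure, untested, may contribute.

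The first axis of the deviations from group means held 33.1% of the within-group variance over 9795 probe sets, against at most 12.7% in 20 shuffled sets. The shuffles treated each probe set on its own and so broke the correlation between genes. They show only that genes deviate together, not that every group shares the axis. Control light replicates 1 and 3 lay at -24.68 and 24.68 on this axis, and low R:FR replicates 1, 2 and 3 at 4.75, -2.82 and -1.93. RNA quality, read from 3′ minus 5′ control levels, correlated with it at r = 0.12 within groups (permutation p = 0.753, adjusted 0.818, rho = 0.1 with permutation p = 0.764, r = -0.29 without the 2 farthest arrays), with an upper bound of 0.63 on its size. Hybridization controls gave r = -0.06 (permutation p = 0.818, adjusted 0.818, rho = -0.04 with permutation p = 0.89, r = -0.15 without the 2 farthest), with a bound of 0.59. Replicate number explained 6.5% of the score's within-group variance over the 12 light arrays, and the tables argue against it there and against both control measures as the main cause. Over the 6 density arrays it explained 86.8%, with 1 sign at each of the 3 numbers, but 2 of the 6 alignments of the numbers gave as much, so it stays open for them; no biological explanation was tested.

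Low R:FR and low blue moved called genes such as COR15A and PORB in opposite directions, 17 opposite against 7 shared. Over all probe sets the covariance was 0.0101, and 36 of 100 simulated unchanged groups with whole-array noise were as low, so an opposition across the transcriptome beyond the shared controls was not shown. Noise independent between probe sets would have put it below the lowest simulated value of 0.0119, but it ignores the correlation between genes. With the axis removed the covariance was 0.0029 and 12 of 100 simulations were as low. Since it did not lie below the simulations before the removal either, this decides nothing about the axis. The direct test of COR15A and PORB sets low R:FR against low blue and uses the control arrays only for the estimate of spread. It shows that the treatments differ, but cannot give the direction of either against control light. These genes were named here for their opposite calls against control light. Their direct difference is therefore no separate evidence of opposition.

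Other splits of the same arrays were counted for each number of calls. For the 7 comparisons of 2 groups, 1 of 10 splits, the real one, gave as many calls, and 10 splits are too few for a share under 0.05. Of the canopy splits, 4 part all 3 pairs of the same number, with 1061 calls for the real one and 0 as the highest other with the block, and the other 6 part 1 pair and keep the rest together. The real counts and the highest of the other splits were 968 and 0 for the canopy, 197 and 0 for low R:FR, 132 and 9 for low blue, 514 and 1 for combined, 102 and 0 for combined against low R:FR, 292 and 5 for combined against low blue, and 998 and 0 for low R:FR against low blue. For the canopy effect minus the low R:FR effect, 1 of 100 splits reached 473 (highest other 302), for the difference from low blue 15 of 100 reached 26 (highest other 1208) and for that from combined 5 of 100 reached 182 (highest other 537). These shares do not bear on whether the 2 effects are equal. Splits that mix canopy and single arrays dilute the canopy effect itself and reached at most 12, 28 and 162, and only 4, 12 and 8 other splits kept canopy and single arrays apart, too few for a share under 0.05. Of those, 0, 12 and 4 were as large. The splits with several times the real count kept canopy and single arrays apart, so the structure they follow is the canopy effect, which stays in the contrast by construction. For the interaction the real count was 0, which 100 of 100 splits reach by construction (highest other 166), so they decide nothing.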

How the results depend on the processing

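Tests chosen only after the results were seen were those without 2 control light arrays. The added lists were chosen after the annotation was opened and before any group difference was computed, and all other alternatives were fixed before the data were examined. No called value changed direction under any alternative. Under quantile normalization, median centring, without dim probe sets or without probe sets that can share transcripts, each count of calls and each correlation stayed within 1.5 times or its spread. Signal over background limits the arrays for the 46.8% of probe sets with a mean below 1.5.

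With a log2 change of at least 1 the counts were 346 for the canopy, 97 for low R:FR, 45 for low blue, 197 for combined, 48 for combined against low R:FR, 126 for combined against low blue and 303 for low R:FR against low blue, and canopy calls shared were 23, 22 and 67 with low R:FR, low blue and combined, by construction fewer. Array weights gave 457 for low R:FR and 200 for combined against low R:FR; the cause was not tested. An intensity trend gave 934 canopy calls, 844 of them among the 968, ended 13 and added 6 calls of named genes, and gave 1 interaction call. Fits within each experiment, with fewer arrays behind the spread, gave 773 canopy calls, 661 of them among the 968, ended 32 and added 8 calls of named genes, and gave 1 interaction call. Quantile normalization ended 4 and added 1, and median centring ended 2. Among canopy calls alone, r was 0.135 with low R:FR, 0.742 with low blue and 0.607 with combined, over genes picked for their canopy change. Without control light replicates 1 and 3, low R:FR had 37 calls, low blue 18 and combined 112, with 1 control array left that is assumed to vary like the other groups. List shifts went from 20 to 11, and in the added lists from 35 to 8, with an estimated correlation. None of the fixed or added lists then passed in the canopy (4 and 6 before), low blue (2 and 1) or the interaction (1 and 0). In low R:FR against control light the 3 shifts of fixed lists stayed and the 4 of added lists ended.

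Leaving out 1 array gave 554 to 825 calls for the canopy, 80 to 472 for low R:FR, 30 to 130 for low blue, 276 to 681 for combined, 52 to 68 for combined against low R:FR, 124 to 332 for combined against low blue, 569 to 960 for low R:FR against low blue and 0 to 0 for the interaction. Canopy minus low R:FR gave 322 to 591, minus low blue 13 to 77 and minus combined 73 to 247. The correlations were 0.004 to 0.152, 0.4 to 0.482 and 0.285 to 0.396, shared calls 21 to 65, 21 to 72 and 106 to 196 (low R:FR, low blue, combined), and list shifts 17 to 23 and 29 to 51 in the added lists. Among values of named genes with 1 array left out, 339 lost and 19 gained the call and 2762 did neither. The 2762 include genes not called in the main fit, which had no call to lose. The share of calls lost is therefore larger than these numbers give.

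With the replicate number as a block the counts were 1061 for the canopy (874 of them among the 968 without it), 229, 151 and 563 for low R:FR, low blue and combined, 122 and 306 for combined against each, 1055 for low R:FR against low blue, 0 for the interaction, and 568, 40 and 196 for the canopy minus low R:FR, low blue and combined effects. For the density arrays, which may be paired, the block brought HAT2 past the threshold in the canopy and moved the difference from low blue from 26 to 40. The block changed no other canopy call reported here, lists included. Over all 180 named genes it added 6 canopy calls and ended 1, added 3 and ended 3 for canopy minus low R:FR, and added 1 and ended 2 for canopy minus combined. Same-number light arrays deviated together at r = -0.46 to 0.405 in 18 pairs, of which 6 were over 0.1, and 5 of 12 arrays correlated best with their own number, so the light numbers were not read as pairs.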

Other observations

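The 30 added gene lists were chosen after the annotation was opened, and the genes named from them were chosen after their values were seen.

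UGT78D2, a flavonoid glucosyltransferase gene, had a log2 change of -1.05 ± 0.16 in the canopy (limma adjusted p = 0.00089) and rose by 1.16 ± 0.16 in low R:FR (0.0014), a difference of -2.22 ± 0.23 (0.00011). CHIL had -1.21 ± 0.31 in the canopy (0.035) and was higher in low R:FR than in low blue by 1.98 ± 0.31 (0.00095). The 8 flavonoid and anthocyanin genes shifted down in the canopy (adjusted p = 0.0021; adjusted p = 0.1 with an estimated correlation) with 3 called lower. They were lower in combined than in low R:FR, with 3 called (adjusted p = 0.00019; adjusted p = 0.041 with an estimated correlation). In low R:FR against low blue 3 were called higher, with a median of 0 (list adjusted p = 0.012; adjusted p = 0.19 with an estimated correlation). The list did not shift in low R:FR, low blue or combined against control light (adjusted p = 0.078, 0.078 and 0.28), but passed in low R:FR (0.011) and low blue (0.021) without dim probe sets.

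Autophagy genes, which recycle cell contents, had positive log2 changes in the canopy in 10 of 10 members, of which 1 was called, ATG8C at 0.65 ± 0.16 (adjusted p = 0.025; list adjusted p = 0.0015; adjusted p = 0.37 with an estimated correlation). In low R:FR 0 of 10 changes were positive and 1 gene was called, ATG3 at -0.72 ± 0.16 (list adjusted p = 6.9e-05; adjusted p = 0.18 with an estimated correlation). ATG8E and ATG8F were lower in low R:FR than in low blue by -1.33 ± 0.23 and -0.89 ± 0.18. Tubulin genes shifted up in the canopy, with TUA1 at 0.73 ± 0.15 and TUB5 at 0.57 ± 0.14 (list adjusted p = 0.0011; adjusted p = 0.1 with an estimated correlation), and in low blue with 0 of 7 called (list adjusted p = 0.00021; adjusted p = 0.2 with an estimated correlation). The call of ATG8C ended without single replicate 3 (0.12), as did that of TUA1 (0.063), and that of TUB5 without canopy replicate 2 (0.1). The canopy call of CHIL ended without single replicate 2 (0.15) and that of ATG3 in low R:FR without control light replicate 3 (0.23). That of ATG8F between low R:FR and low blue ended without low R:FR replicate 2 (0.054). Over the 6 leave-outs CHIL lost the call in 5, ATG8C, TUB5 and ATG3 in 4, TUA1 in 2 and ATG8F in 1.

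EXGT-A3, a xyloglucan endotransglycosylase gene, rose in the canopy (1.62 ± 0.12, adjusted p = 1.2e-06), low blue (0.71 ± 0.12, 0.0093) and combined (1.17 ± 0.12, 2.4e-05). EXLA2 rose in low R:FR (0.91 ± 0.2) and combined (1.66 ± 0.2), and EXLA3 in combined (0.87 ± 0.14). The 10 XTH genes of the added list shifted up in combined with 5 called (adjusted p = 1.7e-06; adjusted p = 0.003 with an estimated correlation). In low R:FR 0 were called, and the shift (adjusted p = 0.038; adjusted p = 0.18 with an estimated correlation) ended after quantile normalization (0.057), without control light replicates 2 (0.094) or 3 (0.076) and without low R:FR replicates 1 (0.1) or 2 (0.07). In low blue, where it did not pass (adjusted p = 0.072), it passed without dim probe sets (0.0015). The 18 genes of the wider expansin list shifted up in low R:FR with 1 called (adjusted p = 0.0076; adjusted p = 0.083 with an estimated correlation), which ended without low R:FR replicate 1 (0.1). AFR, an F-box gene of far-red signalling, rose in low R:FR by 1.07 ± 0.19 and in combined by 0.79 ± 0.19. Without 1 array the calls of EXLA2 in low R:FR (0.21, without control light replicate 3) and of AFR in low R:FR (0.062, without low R:FR replicate 2) and combined (0.16, without control light replicate 3) ended. These 3 calls were lost in 4, 3 and 5 of 6 leave-outs. Fits within an experiment also ended the calls of EXLA2 in low R:FR (0.087), AFR in combined (0.051), TUA1 in the canopy (0.065) and ATG3 in low R:FR (0.074), the last also after quantile normalization (0.056).

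Among lists with 1 or 2 named members, PDF1.2 of jasmonate response differed by -3.56 ± 1.42 in the canopy (adjusted p = 0.23) and BCAT4 of glucosinolate synthesis by -3.23 ± 0.95 in combined (0.1), neither called. BCAT4 had -2.78 in the canopy, not called in the main fit but called in a limma fit of the density arrays alone (adjusted p = 0.044). No control probe set of 64 was called by limma in any of the 8 comparisons within an experiment, with 1 to 11 at an unadjusted p under 0.05. The highest numbers were 11 for combined against control light and 10 each for combined and low R:FR against low blue. The 3′ minus 5′ level was 2.24 ± 0.02 in low R:FR and 2.28 ± 0.03 in combined, against 2.37 ± 0.1 in control light and 2.38 ± 0.11 in low blue. Hybridization controls gave 6.99 ± 0.01, 6.96 ± 0.23, 7.14 ± 0.09 and 7.13 ± 0.19 in that order. Whether this bears on the comparisons was not tested.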
